A study of Mus musculus with 6 samples.

How the data were processed

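The study measured mRNA with expression arrays in 2T3 cells, a mouse pre-osteoblast line, grown in OptiCells, which are closed culture cassettes with gas-permeable walls. Total RNA from 3 static samples and from 3 samples exposed on a Random Positioning Machine was profiled, with 1 array per sample. A Random Positioning Machine rotates cultures so that the direction of gravity averages out over time, and the labels call this condition simulated microgravity. The length of exposure, the scanner and the array maker are not given in the sources used here.

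The deposited table holds intensities on a linear scale, 1 per probe and array, for 10500 probes on each of the 6 arrays. What the authors did to the scanner values is not given in the sources used here, so the following comes from the deposited values alone. The deposited medians were 0.927, 0.909 and 0.908 for static 1, 2 and 3 and 0.909, 0.915 and 0.919 for microgravity 1, 2 and 3. They lay within 2.07% of each other, so the table was treated as already scaled between arrays. How it was scaled stays unknown. Between 0 and 6 values per array were below 0. Between 68 and 163 cells per array were empty, with the most on static 2 (134) and microgravity 2 (163). No detection call or control-probe label was used, so no probe was removed as a control and no intensity was called absent.

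Each array was divided by its median, values under 0.1 of the median were set to 0.1, and log2 was taken. This floor held 6.44% of the values of microgravity 2 and 9.16% of static 2, against 17.1% to 19.8% on the other arrays. Probes at the floor on every array (290) and probes with fewer than 2 values in a group were left out, which removed 354 probes and left 10146. Fold changes are differences of mean log2 values, simulated microgravity over static, and the floor understates changes of dim probes. No further normalization was applied in the reported fit, since the arrays shared a median.

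Groups were compared with limma (version 3.58.1 in R 4.3.3), using lmFit and eBayes with an intensity trend, a 2-sided test, Benjamini-Hochberg adjustment over the 10146 probes and a threshold of 0.05. Standard errors (SE) are from this fit, and their median over probes was 0.23 on the log2 scale. The number of arrays, 3 per group, limits the precision. Group values are given as intensity relative to the array median, mean ± SD over 3 arrays. The labels do not say that the samples of a group came from separate cultures or days, so the p-values measure only the spread between these samples, which may be technical.

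Gene symbols came from GEO's platform annotation. Of the 10500 probes, 8983 had 1 gene symbol, 1 had several and 1516 had none and stayed unnamed. Gene identifiers of 8975 probes were found in an NCBI gene table of the mouse assembly, those of 9 were not and kept the annotation's symbol, and 0 symbols changed. No coordinates are given, because the build behind the probes is not given in the sources used here. A gene was represented by the probe with the highest mean, which gave 8588 genes. Of the 130 genes with several probes, 40 had probes of opposite sign, 0 of them among the called genes.

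The test, the settings and 27 gene lists were fixed before the data were examined. Lists were tested with limma's camera on the moderated statistics with a preset correlation of 0.01 between genes, adjusted over the 27 lists. The alternatives were camera with an estimated correlation, and fry, another limma set test, which does not compare a list with other genes. All other settings kept camera's preset correlation, so the number of alternatives a list passed says little about that choice. Counts of list members past the threshold are given over all probes and adjusted over the list alone. The genes named were also set by a rule. It took up to 12 genes in each direction with the largest change among those past the threshold whose groups did not overlap and whose brighter group lay above the median of all probes. It added all called members of the osteoblast, proteoglycan and protease lists, a set of osteoblast genes given by value, and up to 4 members of each other list with the smallest p. Genes named outside this rule are said to be so.

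The fit was tested on simulated data with the real probes' static means and limma's moderated spreads. There were 10 simulations of 10146 independent probes with 200 of them changed, all drawn from probes above the array median in static cells. The fit recovered 92.9% of 4-fold and 39% of 2-fold changes, and 4.49% of its calls were false. With 1 static array left out it recovered 78.5% and 12.5%. Recovery of dimmer probes was not tested. The shares also depend on how many probes changed and on the moderated spreads, so they need not hold for the real arrays. On the real arrays 0 probes passed with any 1 array left out. Camera found a list lowered 2-fold in 10 of 10 simulations and made 0 calls in 260 tests of unchanged lists. The simulated probes were independent, so this does not test how often camera calls unchanged lists of correlated genes.

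Alternatives covered the normalization, the floor, filters on dim probes, the variance model, array weights, the replicate number as a block, empty cells, the probe standing for a gene, the threshold, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9.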

Results

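Expression was measured in 6 samples of 2T3 pre-osteoblasts, 3 kept static and 3 exposed to simulated microgravity. The comparison of these groups addresses, per the series title, how simulated microgravity affects the differentiation and gene expression of these cells. Each array carried 10337 to 10432 values. Log2 values of arrays correlated across probes, which are not independent replicates, at 0.97 to 0.99 within groups and at 0.96 to 0.99 between them, so most of the profile was shared. The highest value between groups (0.987) was above the highest within a group (0.985).

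Of the genes past the threshold, 8 stand in the osteoblast, proteoglycan or collagen lists, and all 8 were lower in simulated microgravity. Of 10146 probes tested, 28 passed the threshold, 19 lower and 9 higher in simulated microgravity. The count was 53 to 59 with quantile or cyclic loess normalization, a floor at 0.05 of the median, no floor, or dim probes left out, and 178 with array weights. It was lower, at 19, with eBayes without the intensity trend. It was 0 with the replicate number as a block, and 0 with any single array left out. The 28 probes stood for 24 named genes, 17 lower and 7 higher, while 4 probes had no gene name. At an unadjusted p under 0.05 there were 1100 probes, against 507 expected by chance. Groups did not overlap in 1424 of 8588 genes (16.6%), against 10% by chance. At that unadjusted level 112 probes were at least 2-fold lower and 65 at least 2-fold higher.

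S100b, a calcium-binding protein, fell the most in log2 terms. It went from 3.46 ± 1.08 times the array median (SD, n = 3) in static cells to 0.325 ± 0.0805 in simulated microgravity, which is 10.5-fold lower (log2 change -3.39, SE 0.31, limma adjusted p = 0.0295). Osteomodulin (Omd), a proteoglycan of mineralised matrix, fell 5.53-fold, from 76.8 ± 12.8 to 14.1 ± 4.18. Pth1r, the receptor for parathyroid hormone, had the smallest adjusted p. It fell 5.05-fold, from 5.33 ± 0.408 to 1.06 ± 0.0892 (log2 change -2.34, SE 0.16, limma adjusted p = 0.0194). Alpl, the tissue-nonspecific alkaline phosphatase used as an early marker of osteoblast differentiation, fell 4.74-fold, from 2.85 ± 0.513 to 0.599 ± 0.0847 (log2 change -2.25, SE 0.22, limma adjusted p = 0.0295).

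Col6a3 and Col11a1, chains of collagens VI and XI, fell 4.47-fold and 3.40-fold, and Pcolce2, an enhancer of procollagen processing, fell 2.71-fold. Lumican (Lum) and asporin (Aspn), proteoglycans that bind collagen, fell 3.90-fold and 3.47-fold. The alpha-actinin Actn3 fell 3.19-fold, the prostaglandin E receptor Ptger1 2.96-fold and the aminopeptidase Enpep 2.89-fold. Sfrp2, a secreted Wnt modulator, fell 2.44-fold from 11.3 ± 0.707 to 4.64 ± 0.186. The 3 called genes outside the naming rule were named after their values were seen. They were Clec3b, 5.34-fold lower, Selenop, a selenium transport protein, 2.66-fold lower, and the actin-severing protein Gsn, 2.65-fold lower. SEs of the log2 changes of the called genes lay between 0.12 and 0.31.

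Car6, a secreted carbonic anhydrase, rose the most, by 5.45-fold from 5.58 ± 1.03 to 31.1 ± 10.3 (log2 change 2.45, SE 0.26, limma adjusted p = 0.0378). The cytochrome P450 gene Cyp4b1 rose 3.94-fold and the hormone gene Fgf21 3.20-fold, both from below the array median in static cells (0.422 ± 0.0630 and 0.411 ± 0.0118). Cox6a2, the muscle form of a cytochrome c oxidase subunit, rose 2.67-fold, and Cth, which makes cysteine from cystathionine, 2.46-fold. Dus4l, a tRNA dihydrouridine synthase family member, rose 2.38-fold. Sgk1, a kinase induced by serum and glucocorticoids, rose 2.17-fold from 3.43 ± 0.224 to 7.45 ± 0.102. No probe passed the threshold (0 by limma, lowest adjusted p = 0.0613) when any 1 of the 6 arrays was left out, static 1, 2 or 3 or microgravity 1, 2 or 3, with 761 to 968 probes then at an unadjusted p under 0.05.

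**Figure D1:**
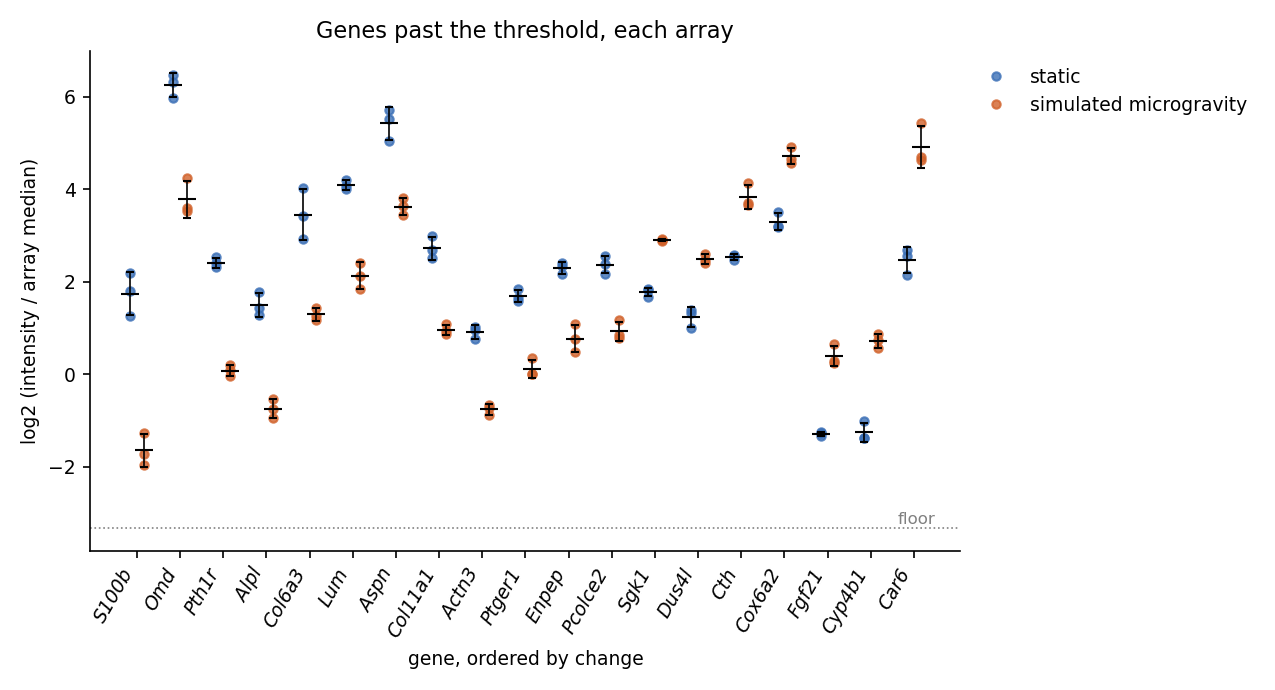
Intensity relative to the array median, on a log2 axis, of the 19 genes past the threshold that the naming rule took for the size of their change, by array. Points are single arrays (3 static, 3 simulated microgravity), bars are the mean and SD of log2 values, and the dotted line is the floor of 0.1. The groups do not overlap for any of these genes, a condition of the naming rule, and 12 of the 19 are lower in simulated microgravity.

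Of the 27 gene lists, 11 passed by camera, 8 lower and 3 higher in simulated microgravity, and 1 of them passed with an estimated correlation. Small leucine-rich proteoglycans, which bind collagen in the matrix, were that list, and they shifted lower. Of 11 measured members, 4 fell, 0 rose and 7 did not pass, and 9 fell adjusted over the list alone. All 11 had lower values in simulated microgravity, also after quantile and cyclic loess normalization, with a median log2 change of -1.16 (camera adjusted p = 1.30e-14, adjusted p = 0.0274 with an estimated correlation). This list passed in 22 of 22 alternatives, with medians of -1.26 to -1.07. Over the 20 alternative fits at most 1 member was higher, and as few as 8 were measured. The 4 were Omd, Lum, Aspn and osteoglycin (Ogn), the last 2.60-fold lower from 55.9 ± 10.1 to 21.3 ± 0.186. Named after their values were seen, decorin (Dcn) had 77.8 ± 3.77 in static cells and 43.7 ± 0.438 in simulated microgravity (limma adjusted p = 0.0903), and Prelp had a ratio of 0.451 (adjusted p = 0.0621). Biglycan (Bgn), also named after its values were seen, had 43.6 ± 3.53 in static cells and 40.2 ± 1.72 in simulated microgravity (log2 change -0.12, 95% interval -0.45 to 0.22).

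Osteoblast and mineralisation genes also shifted lower, with 2 of 18 measured members past the threshold. Pth1r and Alpl fell, 0 rose and 16 did not pass, and adjusted over the list alone periostin (Postn, named after its values were seen) made 3. The median log2 change was -0.27 (camera adjusted p = 1.05e-04, adjusted p = 0.105 with an estimated correlation), and 6 members had higher values. The list passed in 21 of 22 alternatives, with medians of -0.51 to -0.22. Bone sialoprotein (Ibsp) was dim in both groups, at 0.230 ± 0.0673 and 0.220 ± 0.0616. Its log2 change was -0.05 (SE 0.31), with a sign that turned when static 1, static 3 or microgravity 2 was left out and with array weights. Col1a1, the main chain of type I collagen, had 33.1 ± 11.3 in static cells and 20.5 ± 7.69 in simulated microgravity, a difference within the spread between arrays (log2 change -0.71, 95% interval -1.62 to 0.20, limma adjusted p = 0.631). Runx2, Sp7, Bglap and Spp1 had no probe with that single symbol in the annotation used here and were not analysed here.

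The list of fibrillar collagens and their processing also holds chains of collagen VI, which is not a fibrillar collagen. Of its 26 measured genes, Col11a1 and the collagen VI chain Col6a3 fell, 0 rose and 24 did not pass, and 3 fell adjusted over the list alone. The list's median log2 change was -0.39 with 21 members lower (camera adjusted p = 4.54e-07, adjusted p = 0.105 with an estimated correlation), and it passed in 20 of 22 alternatives, with medians of -0.49 to -0.35. Of 27 bone matrix proteases and inhibitors, 0 passed over all probes. Adjusted over the list alone 1 rose and 2 fell, and the median of -0.05 did not stand apart (camera adjusted p = 0.392). The gene higher on that scale was cathepsin K (Ctsk), a collagen-degrading protease, named after its values were seen. It had 3.49 ± 0.634 in static cells and 5.79 ± 0.437 in simulated microgravity, a ratio of 1.67 (limma adjusted p = 0.166 over all probes).

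**Figure D2:**
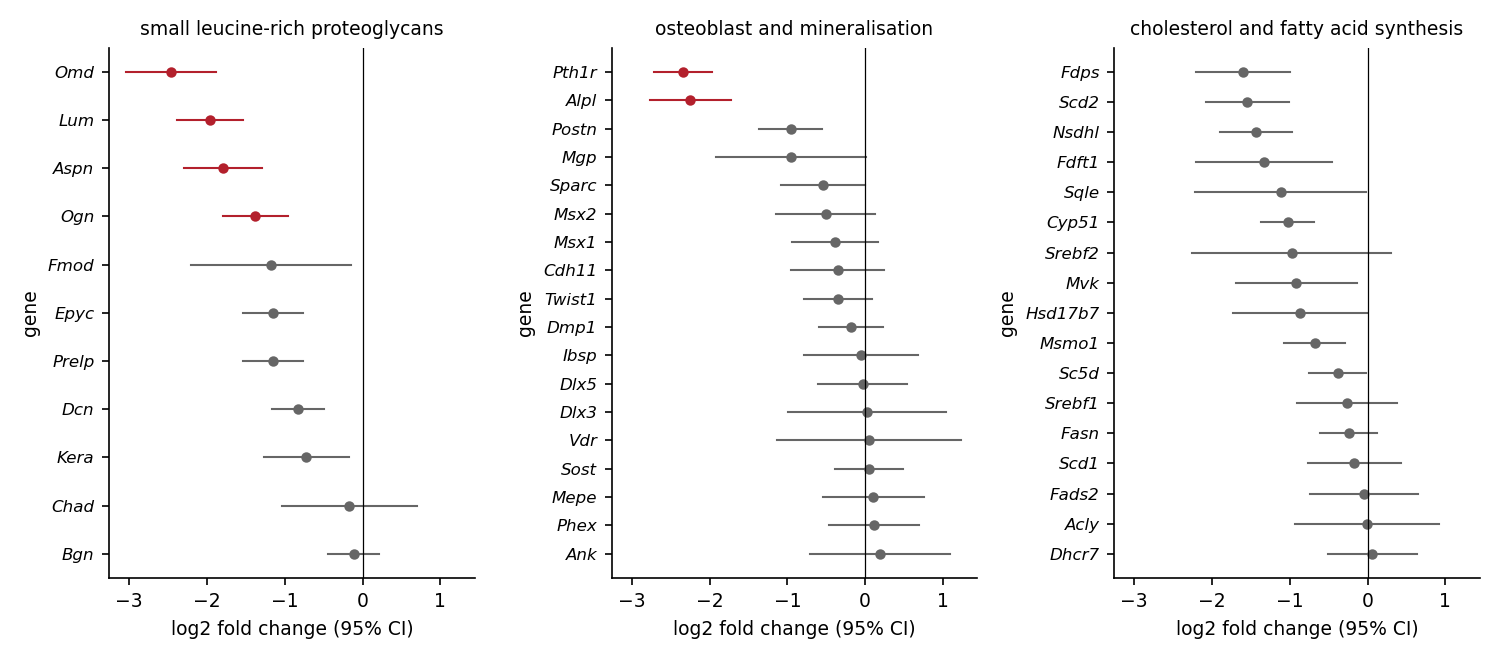
Log2 fold change (simulated microgravity over static) with its 95% confidence interval (CI) from limma for each measured member of 3 gene lists, with genes past the threshold over all probes in red and the others in grey. All 11 proteoglycan genes lie below 0, while the osteoblast list holds Pth1r and Alpl far below 0 and 16 members that did not pass.

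Genes of cholesterol and fatty acid synthesis shifted lower. Of 17 measured members, 16 had lower values, 0 passed over all probes and 6 fell adjusted over the list alone, with a median log2 change of -0.87 (camera adjusted p = 1.68e-09, adjusted p = 0.105 with an estimated correlation). The list passed in 21 of 22 alternatives, with medians of -0.93 to -0.53. The members with the smallest p were Nsdhl and Cyp51, enzymes of late cholesterol synthesis, at ratios of 0.371 and 0.490, the fatty acid desaturase Scd2 at 0.342, and Fdps, which makes farnesyl diphosphate, at 0.331. Their limma adjusted p-values over all probes were 0.0559 to 0.0817.

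Oxidative stress defence genes shifted lower by camera (median -0.21, camera adjusted p = 0.00434, adjusted p = 0.521 with an estimated correlation), but members went both ways. The list passed in 20 of 22 alternatives, with medians of -0.33 to -0.11. Of 30 measured, 0 passed over all probes, while 5 fell and 3 rose adjusted over the list alone. The glutathione transferases Gsta4 and Gstt1 had ratios of 0.372 and 0.354. Genes of the p53 response and apoptosis (28 measured, 0 past the threshold over all probes) had 5 lower and 1 higher adjusted over the list alone, among them the death receptor Fas at a ratio of 0.501. Their median was -0.16 (camera adjusted p = 0.00437, adjusted p = 0.325 with an estimated correlation), and the list passed in 20 of 22 alternatives, with medians of -0.30 to -0.13. Of 46 cell cycle genes, 31 had lower values, 0 passed over all probes and 1 fell adjusted over the list alone (median -0.12, camera adjusted p = 0.00920, adjusted p = 0.128 with an estimated correlation). The cell cycle list passed in 17 of 22 alternatives, with medians of -0.15 to -0.08. Its gene lower on that scale was the proliferation marker Mki67, with 34.1 ± 1.86 in static cells and 19.2 ± 2.60 in simulated microgravity. Growth factor and hormone genes of osteoblasts (32 measured, 0 past the threshold) had a median of -0.07 (camera adjusted p = 0.0462, adjusted p = 0.222 with an estimated correlation), and 1 fell adjusted over the list alone. It was the platelet-derived growth factor receptor Pdgfra, with 52.2 ± 9.80 in static cells and 19.8 ± 2.16 in simulated microgravity (limma adjusted p = 0.0521 over all probes). The growth factor list passed in 10 of 22 alternatives, with medians of -0.21 to -0.03.

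The shift was higher for 3 lists, none of which (0) kept its call with an estimated correlation or had a member past the threshold over all probes. Cytosolic chaperones had a median log2 change of 0.41 with 19 of 24 members higher (camera adjusted p = 0.00434, adjusted p = 0.222 with an estimated correlation), and passed in 20 of 22 alternatives, with medians of 0.29 to 0.45. The chaperonin subunit Cct2 rose (ratio 1.58) and the small heat shock protein Cryab fell (ratio 0.348) adjusted over the list alone. Of 22 endoplasmic reticulum stress genes, 3 rose adjusted over the list alone, Ero1a, Ppp1r15a and Atf3, at ratios of 2.33, 1.99 and 1.92. That list's median was 0.15 (camera adjusted p = 0.0462, adjusted p = 0.521 with an estimated correlation), and it passed in 7 of 22 alternatives, with medians of 0.08 to 0.23. Ribosomal protein genes had higher values in 46 of 47 cases, with a median of 0.29 (camera adjusted p = 1.05e-04, adjusted p = 0.653 with an estimated correlation). The list passed in 19 of 22 alternatives, with medians of 0.11 to 0.45 and up to 12 members lower. Its members had an estimated correlation of 0.52, above the preset that most of these alternatives kept. The call was lost with the estimated correlation and with fry (fry adjusted p = 0.441). The list also did not pass without microgravity 3, where its median was 0.11 (camera adjusted p = 0.189). Arrays of 1 group differed in these genes by as much as the groups did. Their median deviation from the group mean was 0.22 on static 1 and -0.14 on static 3, and 0.37 on microgravity 3 and -0.22 on microgravity 2.

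Of the 16 lists that did not pass by camera, Wnt signalling (32 measured, median -0.06) held 1 called gene, Sfrp2, and the others held 0. Actin cytoskeleton genes (28 measured) had 14 members with higher and 14 with lower values. Their examples included the matricellular gene Ccn2 at a ratio of 1.72 and the tropomyosin Tpm1 at 0.702, neither past the threshold. Among inflammatory cytokines and chemokines (median -0.07), 2 rose and 3 fell adjusted over the list alone, with Ptx3, an acute-phase pentraxin, at 118 ± 6.26 in static cells and 259 ± 62.9 in simulated microgravity. Among immediate early genes (median 0.06) 3 rose on that scale, with the transcription factor genes Fosl1 and Myc at log2 changes of 1.21 and 0.59. Of integrins and adhesion genes 4 fell on that scale, among them the syndecan Sdc2 and tenascin C (Tnc) at ratios of 0.509 and 0.591.

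Medians were -0.14 for microtubules and intermediate filaments, 0.22 for hypoxia and glycolysis, 0.02 for mitochondrial respiration and -0.09 for the interferon response. Of the lists that did not pass, integrins and adhesion passed in 4 of 22 alternatives, the interferon response in 3 of 22, microtubules and intermediate filaments, hypoxia and glycolysis, and Wnt signalling in 2 of 22 each, and the others in 0. BMP and TGF-beta signalling (0.03) and integrins and adhesion (0.04) had medians above 0 while camera pointed lower, as did the adipocyte and skeletal muscle lists. Marker lists of cell types other than osteoblasts had medians of 2.6e-05 for adipocytes, -0.07 for chondrocytes, 0.01 for skeletal muscle, 0.07 for macrophages, osteoclasts and blood cells, and 0.11 for endothelium and epithelium, with 0 members past the threshold. The medians of the actin, BMP, integrin, mitochondrial, adipocyte and skeletal muscle lists took the opposite sign under quantile or cyclic loess normalization.

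**Figure D3:**
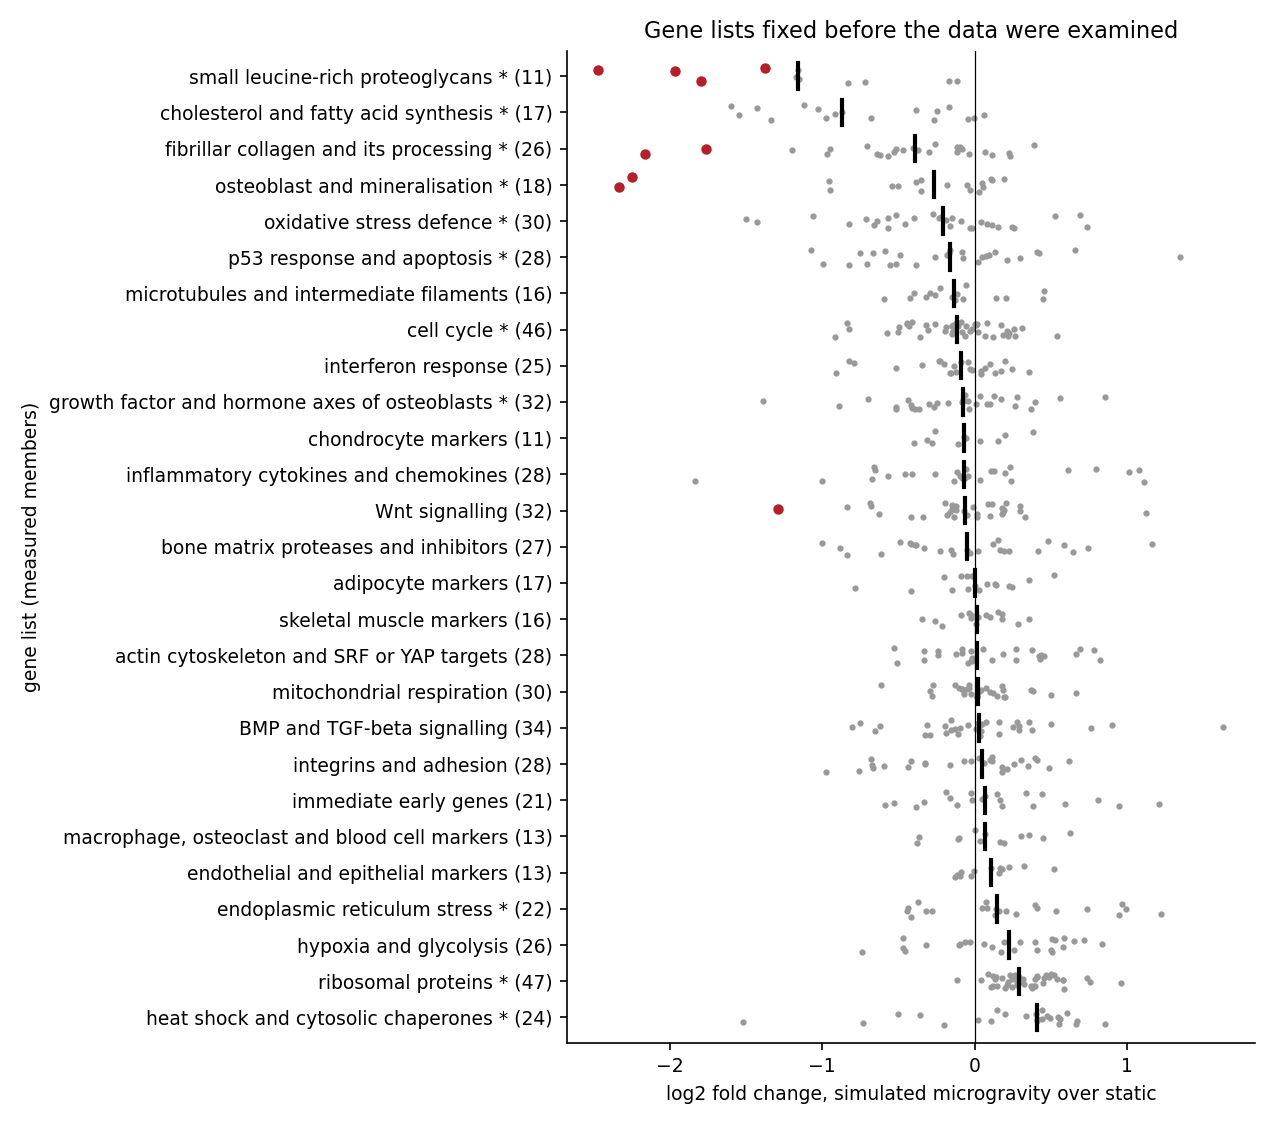
Log2 fold change (simulated microgravity over static) of each measured member of the 27 gene lists, with the number measured in brackets. Red points passed the threshold over all probes, black bars are list medians and asterisks mark the 11 lists past the camera threshold, with the proteoglycan list at the lowest median (-1.16) and cytosolic chaperones at the highest (0.41).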

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

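The alternatives without static 2 and microgravity 2 together, and with the floor at 0.2 of the median and quantile normalization, were chosen after seeing the data, as was leaving out shared members of the ATF4 and ERK lists. The 28 probes, 24 genes and 11 lists became 54, 48 and 12 with quantile normalization, 57, 48 and 10 with cyclic loess normalization, and 56, 49 and 9 with the floor at 0.2 of the median and quantile normalization. Probes and genes were 53 and 47 with the floor at 0.05 of the median, 56 and 50 with no floor, 59 and 53 with the dimmest 25% of probes left out, 54 and 48 with the dimmest 50% of probes left out, and 178 and 160 with array weights. An adjusted p under 0.1 gave 121 probes, and unadjusted p under 0.05 and at least 2-fold gave 177. Lists were 1 with an estimated correlation in camera and 4 with fry in place of camera. The estimated correlation lay below the preset 0.01 for the osteoblast (-0.019), cell cycle (-0.015) and growth factor (0.0017) lists. Correlated members are thus not why those calls were lost. The other lists that lost their call had 0.027 (chaperones) to 0.52 (ribosomal proteins). The other settings kept the counts within 1.5 times, but of the called probes and genes, 16 and 14 kept their call with eBayes without trend, 26 and 23 with the floor at 0.5 of the median and 27 and 23 with eBayes robust. With the dimmest 50% left out 22 and 19 did. All 24 called genes kept their direction in each of the 19 or 20 alternative fits in which they were measured. Leaving out or weighting arrays could not turn a sign, as no called gene's groups overlapped, and the variance model does not alter log2 changes. The dim end of the arrays, where up to 19.8% of values sat at the floor, limits what could be measured there.

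Leaving out 1 array gave 0 to 0 probes and 0 to 0 genes by limma (761 to 968 probes at an unadjusted p under 0.05) and 8 to 11 lists. In the fit without static 2 and microgravity 2 together there were 0 probes and 0 genes by limma, with 848 probes at an unadjusted p under 0.05, and 11 lists. With the replicate block there were 0 probes past the threshold and 0 genes by limma, 931 probes at an unadjusted p under 0.05, and 9 lists. The labels do not say whether the numbers pair the samples. Same-numbered arrays had correlations of deviations of -0.21, 0.46 and -0.18, and not every array correlated best with its own number. Deviations are tied within a group, so these correlations cannot decide it. In each group the array numbered 2 had the most empty cells and the smallest share of values at the floor. Empty cells also ranked the replicate numbers in the same order in both groups. Whether the numbers mark shared processing stays open. For these changes in the counts the cause was not tested.

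Genes that took the opposite direction, and lists for which camera's direction turned, were not called in any setting. Mitochondrial respiration had a median of -0.0419 with quantile normalization, -0.0580 with cyclic loess and -0.0419 with the floor at 0.2 and quantile normalization together, and -0.0957 to 0.134 with 1 array left out. Skeletal muscle markers turned in camera's direction with the replicate block and with probes complete on all 6 arrays (0.0198 in both), with the floor at 0.2 and quantile normalization together (0.00189), and with an estimated correlation and fry (0.0126 in both), and ranged from -0.0654 to 0.114 with 1 array left out. Without static 2 and microgravity 2, adipocyte markers were at 0.0834, endothelial and epithelial markers at -0.00885 and the gene Cldn5 at -0.0177. With array weights Ibsp was at 0.0197 and Cldn5 at -0.0486, and with the dimmest 50% of probes left out macrophage, osteoclast and blood cell markers were at -0.0361. With 1 array left out the ranges were -0.0424 to 0.106 for adipocyte markers, -0.0937 to 0.163 for endothelial and epithelial markers, 0.0524 to 0.182, turning in camera's direction only, for actin genes and -0.323 to 0.112 for Ibsp. The cause was not tested.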

Other observations

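The tests of other cell types, of lists without shared members, of shared replicate numbers and of low-end background below were chosen after the result was seen, and so was the comparison of the medians of the 3 lists below with other splits of the arrays. Genes of ribosome biogenesis, a group not among the lists fixed beforehand, had higher values in simulated microgravity. Fbl, Pus7 and Ifrd2, near the top of the genes with higher values, prompted a list of nucleolar and pre-ribosome genes without those 3. All 30 measured members had higher values, with a median log2 change of 0.69. None (0) passed over all probes and 17 did adjusted over the list alone. Examples, named after their values were seen, are the nucleolar helicase Ddx21 (6.07 ± 1.02 in static cells and 12.2 ± 1.92 in simulated microgravity), Nop56 (10.5 ± 0.919 and 19.1 ± 2.34) and nucleolin (Ncl, 52.1 ± 5.21 and 84.2 ± 11.5). The list passed by camera (adjusted p over 3 such lists 6.03e-16) and with an estimated correlation (adjusted p = 0.0194). Its median ranged from 0.56 to 0.70 over 20 alternatives, with at most 1 member lower in any of them. The largest median in size from the other splits of the arrays was 0.31. Each of those splits mixes the groups unevenly, so it still holds part of the group difference and sets no chance level. These values are consistent with a wider rise of ribosome biogenesis genes, a hypothesis found and tested on the same 6 arrays.

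Fgf21 and Cth, both among the genes that rose, prompted a second list. They are known targets of the transcription factor ATF4, which responds to amino acid shortage and endoplasmic reticulum stress. A list of other ATF4 targets, leaving out Fgf21, Cth, Ero1a and Ppp1r15a, had higher values for all 27 measured members and a median log2 change of 0.37 (camera adjusted p = 1.12e-08, adjusted p = 0.0779 with an estimated correlation). None (0) passed over all probes and 5 did adjusted over the list alone, and 6 members also stand in lists fixed beforehand. Without those the median was 0.32 over 21 members (camera adjusted p = 2.84e-06, adjusted p = 0.0856 with an estimated correlation). Another split of the arrays gave a median of 0.31 in size, though it too holds part of the group difference. As the list did not pass with an estimated correlation, a wider rise of ATF4 targets is a candidate explanation that these arrays test only weakly. For Ereg, Hbegf, Fosl1 and Plaur, seen with higher values, a list of ERK feedback genes and other EGF receptor ligands, also without Lif and Il11, had a median of 0.38 with 15 of 16 members higher (camera adjusted p = 0.00122, adjusted p = 0.0779 with an estimated correlation). The only ligand measured in it, Tgfa, had a log2 change of 0.02 (named after its values were seen), so the list does not speak of other ligands. It shares 3 members with lists fixed beforehand, without which the median was 0.36 over 13 (camera adjusted p = 0.00631, adjusted p = 0.0856 with an estimated correlation). All 3 lists met the criterion written for them (camera adjusted p under 0.05 and a median above 0.2). For the ERK list another split, which also holds part of the group difference, gave 0.40 in size. The ERK list did not pass with an estimated correlation, so this hypothesis stays undecided.

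The fall of the small leucine-rich proteoglycans was weighed against intensity-dependent scaling and against cells of another type replacing the osteoblast line. Of 10000 random lists matched on mean expression, 0% had a median as low as -1.16, which argues against scaling that acts on intensity alone. Among 5 marker lists of other cell types the highest median was 0.11, below 0.5, a bound set after the values were seen. The bound was meant for replacement of a large part of the culture. The medians argue against that for those types, but say nothing of a smaller share or of a type the lists do not cover. Some of these markers, such as Pecam1 and Comp, sat at the floor on all 3 static arrays, where changes are understated. A change within the osteoblast line under simulated microgravity, and any handling difference that went with the machine, stay open and were not tested.

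Static 1 and microgravity 3 deviated together from their group means, with a correlation of deviations over 9944 probes, which are not independent replicates, of 0.66. It was 0.46 for static 2 with microgravity 2 and 0.38 for static 3 with microgravity 1. Deviations sum to 0 within a group, which ties these correlations to one another but does not by itself make any of them as large as 0.66. What lay behind that value, a shared batch included, was not tested, and no value without a batch could be computed from these arrays. As the whole cause of the first value, intensity-dependent scaling between arrays is argued against, since it was 0.66 after cyclic loess, and so is low-end background, since it was 0.78 among the brighter 4972 probes. The lowest correlation of a same-numbered pair was -0.21, which leaves open whether replicate numbers mark shared cultures or days, and no biological explanation was tested.

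The 6 arrays have 10 splits into 3 and 3, the real one included, which are too few for a share under 0.05. Each other split mixes the groups unevenly, so it still holds part of the group difference and sets no chance level. The real split was the 1 of the 10 to give as many as 28 probes, 24 genes or 11 lists past the threshold. The highest of the others were 0 probes, 0 genes and 7 lists, and the split with 7 lists set static 1, microgravity 2 and microgravity 3 against the rest.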
